A study of Homo sapiens with 5 samples.

How the data were processed

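RNA from 5 samples of MHCC97H cells, a human hepatocellular carcinoma line, was measured on 5 one-colour arrays. Per the labels' protocols, total RNA was extracted with Trizol, amplified with incorporation of amino allyl nucleotides and coupled to Cy5. The deposited values are probe intensities on a linear scale, and their unit was read from the values themselves. Values below 0 occur on 3 of the arrays, and median intensities lie between 616 and 825. The scanner, the background correction and the scaling that the authors applied to these intensities are not given in the sources used here. The deposited table has 28264 probes. No flags of detection above background were used here, so signal near the floor could not be told from background probe by probe.

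Samples were grouped by the submitters' labels into empty vector (n = 2), ACOT12 (n = 2) and ACOT12 mutant (n = 1). Nothing in the labels says whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No value was identical between arrays. The 1 mutant array was assumed to vary like the other groups, and no replicate check of the mutant exists. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so no such test was run and only the model across genes was tested.

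Probes were named through the platform annotation supplied with the data. Of the 28264 probes, 25893 had 1 gene symbol, 0 had several and 2371 had none. Symbols were looked up by gene identifier in a current gene table, which matched all 25893 and altered 0. No genome build is named for the array, so no coordinates are given.

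Intensities below 0 were set to 0, a pseudocount of 1 was added and log2 was taken, so fold changes are on the log2(intensity + 1) scale. The size of changes that involve readings near the floor depends on this offset. For ACOT12 against empty vector, the difference of 7.15 for the ACOT12 probe became 5.70 with an offset at the 10th percentile. Array medians lay within 0.5 log2 of each other, and by the rule fixed in advance the values were used as deposited, with no further scaling. Each gene was represented by its probe with the highest mean log2 value, which mattered for the 5751 genes with more than 1 probe. Probes whose mean log2 value over the 5 arrays was under the 25th percentile (7.34) were left out, which left 15053 of 19090 genes. One model without covariates was fitted to all 5 arrays with limma 3.58.1 (lmFit and eBayes without trend) in R 4.3.3. It has 2 residual degrees of freedom and a prior of 3.96. All tests were two-sided. Adjusted p-values are limma's after Benjamini-Hochberg adjustment over the 15053 genes, with a threshold of 0.05. Errors of log2 differences are limma's moderated standard errors (SE), and errors of intensities are SDs.

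A collection of 38 gene lists covering acetyl-CoA and lipid metabolism, epithelial and mesenchymal genes, liver functions, growth, stress and signalling responses, and markers of other cell types was tested with camera (preset correlation 0.01, Benjamini-Hochberg over the 38 lists). Camera with an estimated correlation and fry were run beside it, and neither called a list in any comparison (lowest fry adjusted p = 0.273). Of the 995 listed genes, 932 were on the array. Each list's median was also placed among the medians of 10000 random lists of the same size and matched mean intensity.

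The groups, the tests, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule names, per comparison, up to 10 genes in each direction with the largest change among those past the threshold whose groups do not overlap. Where fewer pass, it fills up with the largest changes at an unadjusted p under 0.05, named as not past the threshold. It further names ACOT12, a fixed set of 11 genes of the epithelial-mesenchymal transition, and up to 4 members with the smallest p of each list described. Alternatives were 3 other scalings, other filters, another offset, other treatments of several probes per gene, other variance models, the replicate number as a block and leaving out each array in turn. A pair of alternatives was added after the data were seen: equalizing the background of the arrays, and cyclic loess with a stricter filter.

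The procedure was tested on simulated data of 15053 genes in 20 simulations with 100 changed genes per size. For ACOT12 against empty vector it recovered 12.3% of genes changed by 1 log2 unit and 98.1% of those changed by 3 log2 units, with a mean of 5.1 false calls. For the mutant against empty vector it recovered 2.6% and 95.4%, with a mean of 6.25 false calls. A list of 30 genes raised by 0.3 log2 units was found in 20 of 20 simulations, and 1 of 600 unchanged lists was called. The simulated genes varied independently, without correlation within lists or array differences by brightness. Their spread was drawn without regard to brightness. These rates thus need not hold for the real genes or lists, and a gene without a call may have changed by 3 log2 units or more. ACOT12 itself, 7.15 log2 units above empty vector with ACOT12, did not pass as deposited (limma, adjusted p = 0.122). Figures were drawn with matplotlib.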

Results

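The data set addresses which genes lie downstream of ACOT12, a cytosolic thioesterase that hydrolyses acetyl-CoA to acetate and coenzyme A, in liver cancer cells. MHCC97H cells, a hepatocellular carcinoma line with high metastatic potential, had been made to carry an empty vector (n = 2), ACOT12 (n = 2) or a mutant of ACOT12 (n = 1) and had been selected with puromycin for 1 week. The labels do not say which residue the mutant changes. One array was available per sample, and the number of arrays limits the precision of every value. Median probe intensity was 805 and 700 in the empty vector arrays, 816 and 825 in the ACOT12 arrays and 616 in the mutant array. Across genes, which are not independent replicates, log2 values of the empty vector replicates correlated at r = 0.993 and those of the ACOT12 replicates at r = 0.987. Pairs of an empty vector with an ACOT12 array lay between 0.989 and 0.993, so replicates were no more alike than arrays of these different groups. The mutant array correlated at 0.985 with empty vector replicate 2 and at 0.972 to 0.976 with the other 3 arrays.

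ACOT12 itself had the largest log2 difference from empty vector with either transgene. Its single probe (PH_hs_0025727) read 38.6 ± 29.1 intensity units (SD, n = 2) with empty vector, 4796 ± 88.8 (SD, n = 2) with ACOT12 and 4030 with the mutant. These readings lay at the 11.3th and 6.07th percentile of all probes in the empty vector arrays, at the 78.1th and 78.3th in the ACOT12 arrays and at the 76.6th in the mutant array. The log2 difference from empty vector was 7.15 ± 0.50 (SE) for ACOT12 (limma, adjusted p = 0.122) and 6.90 ± 0.62 for the mutant (adjusted p = 0.0688). The ACOT12 arrays read 0.25 ± 0.62 above the mutant array (adjusted p = 0.873), a direction that turned with median centring (−0.16) and cyclic loess (−0.11). None of these passed the threshold. The empty vector readings (5.91 and 4.25 on the log2 scale) lay near the floor of the arrays and were not shown to be above background, so the size of the differences from empty vector is not resolved: with equalized background they were 5.33 and 5.09, and with an offset at the 10th percentile 5.70 and 5.45. After quantile normalization both differences from empty vector passed, at 6.61 (adjusted p = 0.00372) and 6.44 (adjusted p = 0.00481).

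**Figure D1:**
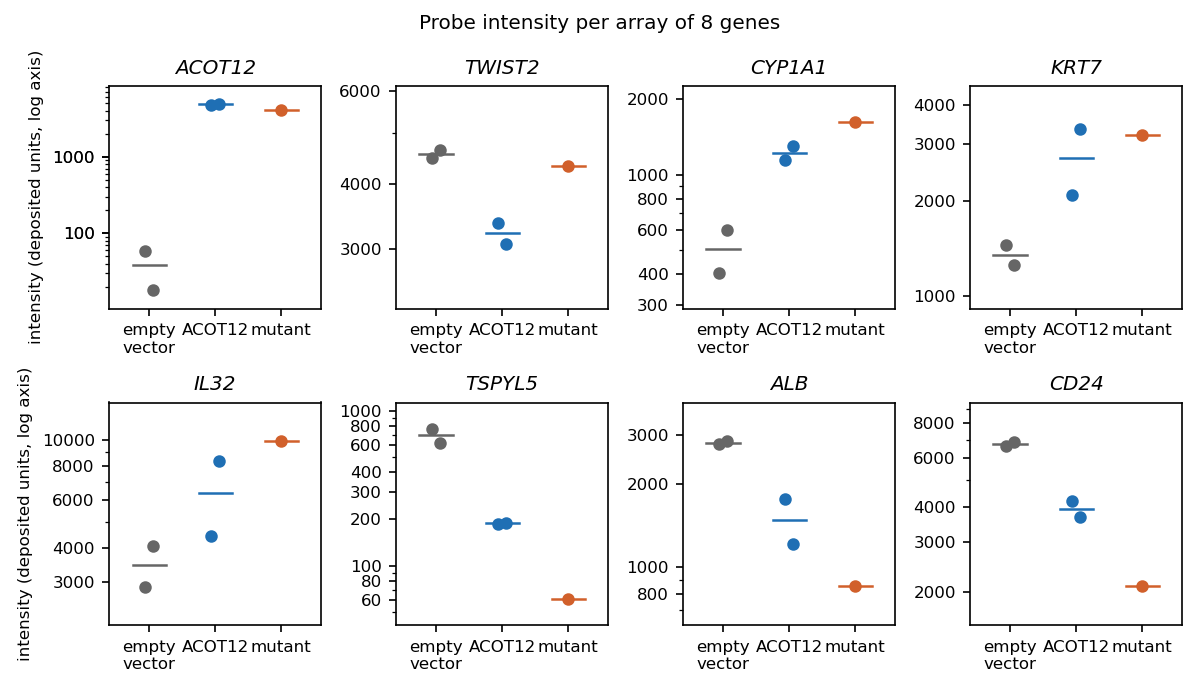
Intensity of 8 genes on each array (points, log axis, deposited units) with the group mean (line) for empty vector, ACOT12 and the mutant, whose group is a single array. ACOT12 read 59.2 and 18.0 with empty vector against 4733 and 4859 with ACOT12, while TWIST2 read lower in both ACOT12 arrays (3369 and 3067) than in the other 3.

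The comparison of ACOT12 with empty vector asks what the enzyme changes. Beyond the transgene, the smallest p belonged to a lower reading of TSPYL5, a TSPY-like nucleosome assembly family member, at 187 ± 3.3 intensity units against 692 ± 103 (SD, n = 2 each), or −1.87 ± 0.17 log2 (adjusted p = 0.270). Albumin (ALB), the main plasma protein made by hepatocytes, read −0.95 ± 0.21, and CD24, a surface glycoprotein of hepatic progenitor cells, read −0.78 ± 0.16. CYP1A1, a cytochrome P450 induced by the aryl hydrocarbon receptor, read 1.31 ± 0.23 higher and KRT7, a keratin of bile duct cells, 0.97 ± 0.26 higher. No gene passed limma's test after adjustment (adjusted p of these 4 genes 0.994), and 452 of 15053 genes had an unadjusted p under 0.05, fewer than the 753 that chance gives. Of those, 384 read higher and 68 lower with ACOT12, a balance that turned to 125 higher and 209 lower after quantile normalization and to 139 and 179 after cyclic loess. The groups did not overlap for 4771 genes (31.7%), where chance gives 33.3%.

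Other genes that read higher in both ACOT12 arrays, none past the threshold, were ITIH5 (1.12 ± 0.15), a hyaluronan-binding protein, FPR3 (1.09 ± 0.18), a formyl peptide receptor, the histone gene H4C13 (1.25 ± 0.43) and the cytokine IL17F (1.08 ± 0.43). DPEP3, a dipeptidase, read 1.26 ± 0.41 higher, the transcription factor ASCL3 1.22 ± 0.31, LRIT1 1.10 ± 0.45 and the keratin-associated protein gene KRTAP4-12 1.08 ± 0.40. Lower readings came from ITM2A (−0.98 ± 0.16), a membrane protein, the BH3-only apoptosis gene HRK (−0.91 ± 0.20), the growth factor CLEC11A (−0.84 ± 0.20) and SNX12 (a sorting nexin, 3333 ± 1346 intensity units with ACOT12 against 6592 ± 102 with empty vector). TTN, FAT3, TNS1 and IL36RN also met the rule for lower genes, but other probes of these genes read the opposite way, for instance −0.98 and 0.40 for TNS1. Most genes that the rule named in this comparison moved the same way with the mutant. Apart from ACOT12, the mutant array lay beyond both empty vector arrays on the same side for 7 of 9 higher and 10 of 10 lower genes. Its differences from empty vector were −1.58 for ITM2A, −1.26 for HRK and −2.55 for CLEC11A, but −1.02 for FPR3 and −1.77 for H4C13. The shared empty vector arrays add to these counts. After quantile normalization the genes past the threshold were ACOT12 and TSPYL5 (−2.16, adjusted p = 0.0357).

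Among regulators of the epithelial-mesenchymal transition, TWIST2 was the one with the smallest p. It read 3218 ± 214 intensity units with ACOT12 against 4557 ± 104 with empty vector (SD, n = 2 each), a log2 difference of −0.50 ± 0.15 that did not pass (unadjusted 0.0163, adjusted p = 0.994). The mutant array read 4321, and the direct difference between ACOT12 and mutant was −0.43 ± 0.19 (adjusted p = 0.255). The adhesion genes CDH1 (−0.02 ± 0.17) and CDH2 (0.09 ± 0.16), the filament gene VIM (0.03 ± 0.17) and the matrix gene FN1 (−0.09 ± 0.15) differed by less than their errors. SNAI1 read 0.08 ± 0.17, SNAI2 0.38 ± 0.20, TWIST1 0.16 ± 0.17, ZEB1 0.16 ± 0.18, ZEB2 0.30 ± 0.20 and EPCAM 0.39 ± 0.24, with adjusted p from 0.994 to 0.999. Of 15 transcription factors of the transition, 10 read higher and 5 lower (camera, adjusted p = 0.509). The 30 epithelial markers (adjusted p = 0.199) and the 27 mesenchymal markers (adjusted p = 0.133) gave no call either, with medians of 0.12 and 0.14.

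Gene lists gave 6 calls of 38, of which 2 were higher and 4 lower, a balance that turned to 6 higher and 1 lower with a filter at the 50th percentile and to 5 higher and 2 lower without ACOT12 replicate 1. The type I interferon response rose with ACOT12 (camera, adjusted p = 0.00253), with 27 of 29 members higher and 2 lower and a median log2 difference of 0.20. This call was lost with an estimated correlation (adjusted p = 0.571) and without ACOT12 replicate 2 (adjusted p = 0.0837). IFIT2 (0.79 ± 0.16), IFIT1 (0.53 ± 0.16), XAF1 (0.58 ± 0.19) and PARP9 (0.55 ± 0.16), all antiviral response genes, had the smallest p, though 0 members passed over all genes or adjusted over the list alone. Replication-dependent histones rose as well (adjusted p = 0.00287), with 22 of 26 higher and a median of 0.28. Adjusted p was 0.571 with an estimated correlation and 0.0823 without ACOT12 replicate 2. Here H1-2 read 0.89 ± 0.26 and H2BC14 0.55 ± 0.16, while H3C1 read −0.82 ± 0.19. After quantile normalization the interferon list stayed past the threshold (adjusted p = 0.0198) and the histones did not (adjusted p = 0.170).

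The other 4 calls (camera) were lower relative to the other genes. They were proliferation (46 genes, median −0.03, adjusted p = 0.00746) and fatty acid oxidation (21 genes, median −0.09, adjusted p = 0.0289). NRF2 and oxidative stress (27 genes, median −0.03, adjusted p = 0.0289) and TGF-beta targets (25 genes, adjusted p = 0.0498) followed. Among lists matched for mean intensity, the median of fatty acid oxidation lay at percentile 0.95. Proliferation lay at 29.95, NRF2 at 39.74 and TGF-beta targets at 37.71, which is not unusual for their brightness. With an estimated correlation adjusted p was 0.571 for proliferation, fatty acid oxidation and NRF2 and 0.633 for TGF-beta targets. Without empty vector replicate 2 none of the 4 passed (0.285, 0.434, 0.608 and 0.135). Without ACOT12 replicate 2 proliferation (0.0837), fatty acid oxidation (0.122) and NRF2 (0.229) did not pass, without ACOT12 replicate 1 fatty acid oxidation (0.153) and TGF-beta targets (0.481), and without empty vector replicate 1 TGF-beta targets (0.0609). In fatty acid oxidation 17 of 21 members read lower, among them DECR1 (−0.25 ± 0.17) and HADH (−0.23 ± 0.16), which act in beta-oxidation. In proliferation CDC25C, a phosphatase of mitotic entry, read −0.28 ± 0.15. AKR1C2, an aldo-keto reductase, read −0.28 ± 0.21. For TGF-beta targets the median (0.01) and the mean (−0.04) differed in sign, with ID1 at −0.41 ± 0.15 and ID3 at −0.39 ± 0.16, both inhibitors of DNA binding. After quantile normalization none of the 4 passed (0.492, 0.290, 0.797 and 0.184).

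Lists on acetyl-CoA and lipid metabolism, the pathway of the enzyme itself, otherwise gave no call. Acetyl-CoA producing and acetate-using enzymes had 14 of 20 members lower (median −0.05, adjusted p = 0.0762), fatty acid synthesis had 13 of 21 lower (median −0.05, adjusted p = 0.0530) with FASN, the fatty acid synthase, at −0.28 ± 0.20, and cholesterol synthesis had 8 of 18 lower (adjusted p = 0.0870). Among 28 histone acetylation writers, erasers and readers 12 read higher and 16 lower (adjusted p = 0.264). Of 42 hepatocyte genes 27 read higher and 15 lower (adjusted p = 0.910). Adjusted over the list alone, ACOT12 among the 11 thioesterases and CD24 among the 17 hepatic progenitor and biliary markers passed. Markers of immune (median 0.24, adjusted p = 0.181), endothelial (0.21, 0.114), fibroblast (0.09, 0.161) and erythroid cells (0.34, 0.187) had positive medians beside these lists, without a call. By brightness of the probe, the ACOT12 arrays read 1.62 and 1.86 log2 units above the empty vector mean in the dimmest 10% of probes and −0.06 and −0.03 in the brightest.

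**Figure D2:**
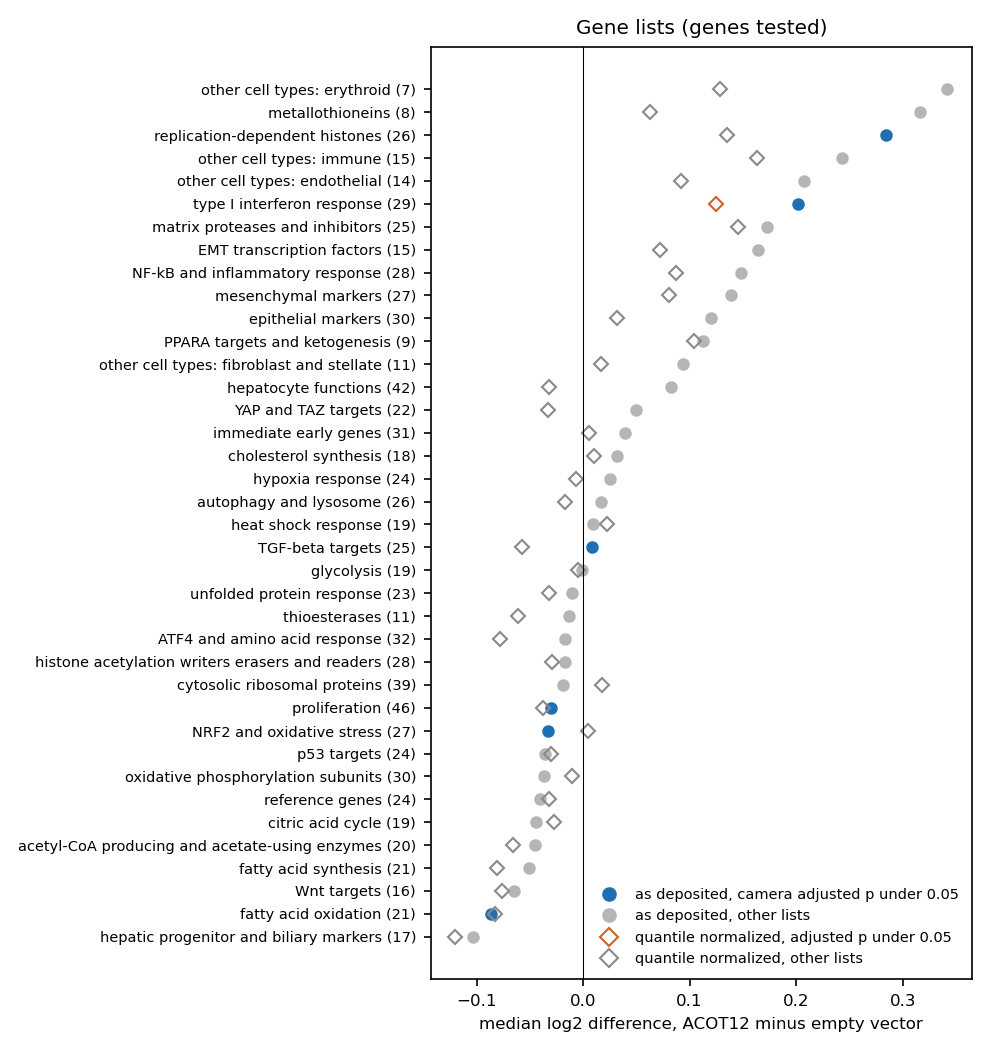
Median log2 difference between ACOT12 and empty vector for each of the 38 gene lists, with the number of genes tested in brackets, as deposited (circles) and after quantile normalization (diamonds). The interferon list (0.20 and 0.12) is coloured under both scalings, and the other 5 lists called as deposited are not coloured after quantile normalization.

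**Figure D3:**
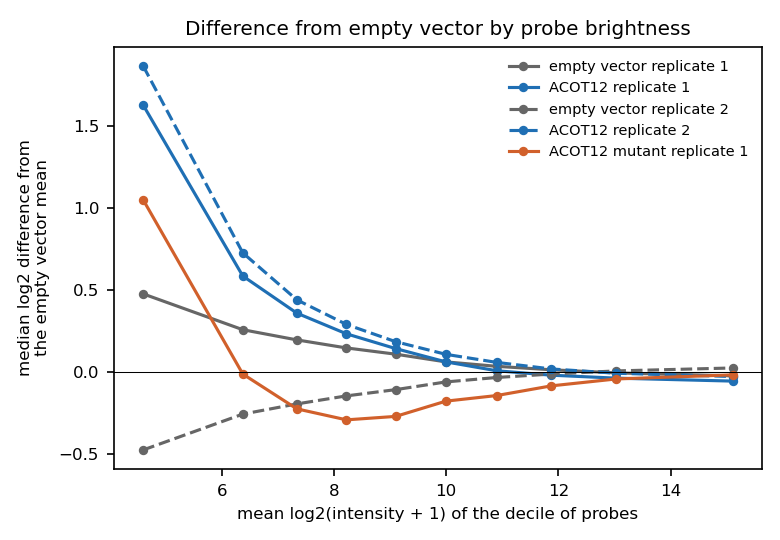
Median log2 difference of each array from the mean of the empty vector arrays, in 10 bins of probes ordered by mean log2 intensity. In the dimmest bin the arrays range from −0.47 (empty vector replicate 2) to 1.86 (ACOT12 replicate 2), and in bin 4 the mutant array lies at −0.29.

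With the mutant, 5 genes passed as lower than with empty vector and none as higher, where ACOT12 itself read 6.90 higher without passing as deposited. KCNJ13, an inwardly rectifying potassium channel, fell from 1092 and 796 intensity units to 21 (−5.41 ± 0.24 log2, adjusted p = 0.00433). The mutant readings of KCNJ13 and NLRP11 (43.8) lay under the 10th percentile of that array (48.4), so the size of their differences is not resolved, with −3.44 and −2.08 under equalized background. IGSF3, an immunoglobulin superfamily membrane protein, fell to 176 (−4.38 ± 0.20, adjusted p = 0.00433), and RNFT1, a ring finger ubiquitin ligase, to 298 (−3.40 ± 0.19, adjusted p = 0.00943). NLRP11, an innate immune sensor of the NLR family, fell by 3.19 ± 0.18 (adjusted p = 0.00943) and TSPYL5 read −3.47 ± 0.21 (adjusted p = 0.00980). TSPYL5 was thereby low with both transgenes, at 61.2 with the mutant. Other probes of IGSF3 (0.22) and RNFT1 (0.63, 0.63 and 0.00) did not show the fall, and a second, dim probe of KCNJ13 read −0.23. Of the 15053 genes 3116 had an unadjusted p under 0.05, 556 higher and 2560 lower as deposited, against 1256 and 1775 after quantile normalization and 1246 and 2108 after cyclic loess.

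Higher readings with the mutant that did not pass included TAGLN (1.95 ± 0.32), an actin-binding protein, MYL9 (1.52 ± 0.23), a myosin light chain, CYP1A1 (1.72 ± 0.28), the inflammatory cytokine IL32 (1.54 ± 0.41, with all 4 probes between 1.34 and 2.15), the cytidine deaminase CDA (1.35 ± 0.19), SPOCD1 (1.41 ± 0.32) and KRT7 (1.25 ± 0.31). UBE2QL1 (2.10 ± 0.22) and DTNBP1 (1.53 ± 0.31) each had another probe that read differently (0.03 and −0.84). GOLGA6L2 read 1.35 ± 0.35, with its other probe at 0.29. Lower readings without a call included VHLL (−2.96 ± 0.40), ENTPD3 (−2.72 ± 0.32), an ectonucleotidase, TNS1 (−2.70 ± 0.26), TTN (−3.43 ± 0.33) and SHPRH (−5.77 ± 2.01), whose probe read 14.6 in this array, near its floor, and 13.4 in ACOT12 replicate 1. The size for SHPRH is thus not resolved (−3.43 with equalized background). TWIST1 read −1.49 ± 0.20 (adjusted p = 0.0814), SNAI2 0.66 ± 0.24, EPCAM −0.77 ± 0.29, CDH1 −0.36 ± 0.21 and VIM 0.26 ± 0.20. TWIST2 (−0.08 ± 0.19), CDH2 (−0.19 ± 0.19), SNAI1 (−0.13 ± 0.20), ZEB1 (0.14 ± 0.22), ZEB2 (−0.14 ± 0.24) and FN1 stayed within their errors. Among hepatocyte genes ALB (−1.72 ± 0.26), FBP1 (−1.44 ± 0.20), a gluconeogenic enzyme, and APOC3 (−1.42 ± 0.29) had the smallest p. Adjusted over the list alone, 6 of 42 hepatocyte genes passed as lower. So did 6 of 14 endothelial and 6 of 11 fibroblast markers, where 2 and 1 passed as higher. CD24 read −1.69 ± 0.19, the chemokine CXCL8 −1.18 ± 0.19 and the iron-binding protein LCN2 −1.51 ± 0.24.

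No list was called for the mutant (camera, lowest adjusted p = 0.0851). The median of all genes was −0.13 as deposited and 0.00 after quantile normalization. Relative to all genes, markers of fibroblasts (−0.63), erythroid (−0.45) and endothelial cells (−0.29) read low in this array, beside 0.35 for the heat shock response. The count of 5 changed with every empty vector or ACOT12 array left out. The ACOT12 arrays enter this comparison only through the shared estimate of the spread. Leaving either out does not change the log2 difference of a given probe. Centring the array medians gave 1446 genes (550 higher, 896 lower).

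Directly compared, 1386 genes were higher with ACOT12 than with the mutant and 3 were lower (limma, adjusted p under 0.05). KCNJ13 (5.63 ± 0.24, adjusted p = 0.00336, with the mutant at the floor and 3.61 with equalized background), VHLL (3.45 ± 0.40), RNFT1 (3.34 ± 0.19), VWCE (3.25 ± 0.46), ENTPD3 (3.13 ± 0.32), H4C13 (3.02 ± 0.53), the transketolase-like gene TKTL1 (2.98 ± 0.38) and SMIM2 (2.81 ± 0.46) had the largest differences, together with IGSF3 and NLRP11. Other probes read 0.17 for IGSF3, 1.00 for ENTPD3, 0.72 for KCNJ13 and −0.59, −0.51 and −0.10 for RNFT1. RNFT1 read −0.47 to −0.70 when any 1 of the empty vector or ACOT12 arrays was left out, as another of its probes was then used. TWIST1, a regulator of the epithelial-mesenchymal transition, was higher by 1.65 ± 0.20 (adjusted p = 0.0349), at 607 and 568 intensity units against 186. It did not pass after quantile normalization. EPCAM, an epithelial adhesion molecule, read 1.16 ± 0.29 (adjusted p = 0.0641), ZEB2 0.45 ± 0.24, CDH1 0.34 ± 0.21, CDH2 0.28 ± 0.19, SNAI1 0.21 ± 0.20, SNAI2 −0.28 ± 0.24, VIM −0.23 ± 0.20, FN1 −0.09 ± 0.18 and ZEB1 0.03 ± 0.22, none past the threshold. Lower with ACOT12 were UBE2QL1 (−2.05 ± 0.22, adjusted p = 0.0349), the kinase gene MAST3 (−0.89 ± 0.20, adjusted p = 0.0470) and TOGARAM2 (−0.85 ± 0.19, adjusted p = 0.0462). The other probe of UBE2QL1 read 0.44. DTNBP1 (−1.06 ± 0.31, other probe 0.78), TAGLN (−1.02 ± 0.32), PTMS (−1.01 ± 0.32), TBX6 (−0.97 ± 0.23), OR2A14 (−0.89 ± 0.34) and GOLGA6L2 (other probe 0.10) read lower without passing.

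Over all genes 1386 of 15053 passed as higher with ACOT12, the share against which counts by list are to be read. It is not matched for brightness, and the called genes were dimmer than all genes tested (median log2 intensity 9.26 against 11). A count above this share in a list of dim genes thus need not set that list apart. None of the genes named in this paragraph passed after quantile normalization. By list, 6 of 42 hepatocyte genes passed, among them APOC3 (1.87 ± 0.29), FBP1 (1.13 ± 0.20), SERPINC1 (1.60 ± 0.29) and CYP8B1 (1.25 ± 0.24). The 3 epithelial markers that passed were CDS1 (1.41 ± 0.29), OCLN (1.76 ± 0.37) and MARVELD3 (1.32 ± 0.29), and the 3 mesenchymal ones COL1A1 (2.13 ± 0.31), ACTA2 (1.73 ± 0.37) and BGN (0.94 ± 0.21). Of the TGF-beta targets 4 of 25 passed (LTBP2 1.56 ± 0.23, ITGB6 1.65 ± 0.30, NOG 1.17 ± 0.22 and ID4 1.23 ± 0.27), of the Wnt targets 3 of 16 (LEF1 1.72 ± 0.30, NKD1 1.50 ± 0.29 and TNFRSF19 1.48 ± 0.30) and of the interferon genes 2 of 29 (IFI44L 1.95 ± 0.27 and XAF1 1.37 ± 0.23). CXCL8 (1.16 ± 0.19) and LCN2 (1.31 ± 0.24) passed among 28 inflammatory genes, and CD24 (0.91 ± 0.19) and ONECUT1 (1.09 ± 0.23) among 17 progenitor and biliary markers. Markers of other cell types also passed: 3 of 15 immune (GNLY, CORO1A and AIF1), 4 of 14 endothelial (STAB1, STAB2, VWF and EMCN), 3 of 11 fibroblast (COL1A1, PDGFRA and ACTA2) and 1 of 7 erythroid (ALAS2). None of these lists was called as a whole.

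The 6 lists called (camera) were all lower with ACOT12 relative to the other genes. Heat shock response had 14 of 19 genes lower (median −0.38 relative to all genes, adjusted p = 0.00865) and cholesterol synthesis 15 of 18 (−0.26, 0.0119). Cytosolic ribosomal proteins had 19 of 39 lower (−0.13, 0.0153) and glycolysis 11 of 19 (−0.15, 0.0281). Unfolded protein response had 11 of 23 lower (−0.12, 0.0296) and reference genes 14 of 24 (−0.19, 0.0350). Among lists matched for mean intensity, the medians of heat shock and cholesterol synthesis lay at percentiles 0.01 and 2.35. Ribosomal proteins lay at 65.19, glycolysis at 30.71, the unfolded protein response at 26.73 and reference genes at 13.63. With an estimated correlation adjusted p was 0.675 to 0.683. Without ACOT12 replicate 1 ribosomal proteins (0.116), glycolysis (0.0857) and the unfolded protein response (0.350) did not pass and the heat shock median went from −0.25 to −0.12, and reference genes did not pass without ACOT12 replicate 2 (0.196) or empty vector replicate 1 (0.0513). For ribosomal proteins (median 0.01, mean −0.05) and the unfolded protein response (0.01 and −0.08) the unadjusted median and the test differed in sign. Among the members with the smallest p were HSF1, the heat shock factor, at −0.44 ± 0.19, EBP, a sterol isomerase, at −0.49 ± 0.18 and PGK1, a glycolytic kinase, at −0.49 ± 0.19, none past the threshold. At an unadjusted p under 0.05 (limma), 1 heat shock member and 1 ribosomal protein read higher with ACOT12 and 0 lower, against the direction of the calls. Cholesterol synthesis and reference genes each had 1 higher and 1 lower, glycolysis 0 and 1, and the unfolded protein response 0 and 0. After quantile normalization or cyclic loess 0 lists passed.

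All 1386 genes also read lower in the mutant than in both empty vector arrays, with a median of −1.21 against the empty vector mean, and 1360 read lower in empty vector replicate 2 than in replicate 1. Their median difference between ACOT12 and mutant was 1.54 as deposited and 1.09 after quantile normalization. On the quantile normalized scale the median of their adjusted p (limma) was 0.061, so many lay just over the threshold. After quantile normalization 5 genes passed (KCNJ13, IGSF3, RNFT1, NLRP11 and MAF), without either ACOT12 array 0 did, and with centred array medians 1339 were higher and 683 lower. The median of all genes moved from 0.13 as deposited to −0.04 with quantile normalization and −0.28 with centring.

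**Figure D4:**
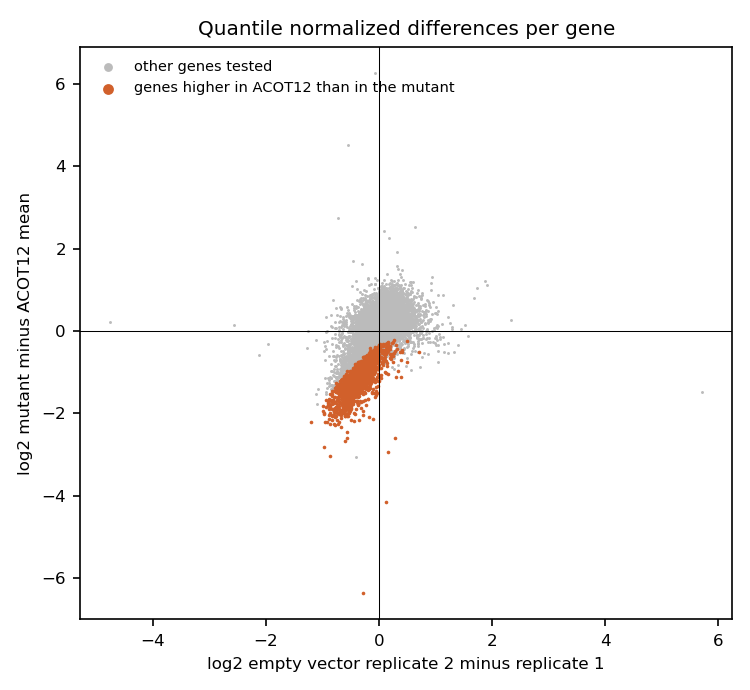
Quantile normalized log2 difference between the mutant and the ACOT12 mean (vertical) against that between empty vector replicates 2 and 1 (horizontal), 1 point per gene tested. Genes higher with ACOT12 than with the mutant as deposited are coloured, and 92.9% of them lie left of 0.

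The effects of both transgenes were set against each other across genes, which are not independent replicates. Log2 differences from empty vector correlated at r = −0.061, where unchanged groups simulated against the same controls gave 0.406. The covariance was −0.0077 against a simulated 0.021. With a different empty vector array for each transgene r was 0.249 one way and −0.44 the other. At an unadjusted p under 0.05, 79 genes read higher with both transgenes (14.2 for independent lists) and 41 lower (11.6). After quantile normalization the balance turned to 52 higher and 72 lower (10.4 and 24.6 for independent lists), and after cyclic loess to 61 and 77 (11.5 and 25.1). Both comparisons use the same empty vector arrays, which adds to these counts and is not allowed for in the values for independent lists.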

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

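All tests in this part were chosen after the results were seen; those on the whole interferon list and on single probes were written down with their bounds before they were computed, and that on its brighter members after other values of the list under that filter had been seen.

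Among probes without a gene name, 4 read at least 2-fold higher with ACOT12 than with empty vector with arrays not overlapping, out of 1653 kept, and 2 read at least 2-fold lower. What these probes detect is not given in the sources used here.

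The 1386 genes that read higher with ACOT12 than with the mutant could stem from the scaling of the mutant array, from signal of genes that liver cells do not transcribe, or from the mutant transgene. Quantile normalization lowered their median difference from 1.54 to 1.094 log2 units. On that scale 811 of them still differed at least 2-fold, and 5 genes passed the threshold. Because the genes were chosen for their difference as deposited in the same arrays, these values cannot decide the part of scaling. Genes of the olfactory, taste, vomeronasal, keratin-associated and defensin families were called 2.421 times as often as genes matched for intensity (33.8% against 14%), and 92.9% of the 1386 genes also read lower in empty vector replicate 2 than in replicate 1 after quantile normalization, against 39.6% of matched genes. The first value fits signal of genes that liver cells do not transcribe, and the second a property of single arrays. With 1 mutant array, a part played by the mutant transgene stays open.

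The interferon list could have risen with ACOT12 through the background level of dim probes or through a response to carrying either transgene. Its median lay at percentile 98.65 of 10000 random lists matched for intensity as deposited and at 99.85 after quantile normalization, the lower of which falls between the bounds of 95 and 99 set for this test. Among the 16 members at or above the 50th percentile of mean log2 value, 15 read higher. Their median of 0.18 (95% interval 0.10 to 0.42, from resampling the genes) lay at percentile 99.94 as deposited and 99.98 after loess. Lists of the same brightness had a median of 0.015 as deposited. The rise of the interferon list under this filter was known before the test was written, so a high percentile was likely. The test therefore cannot decide whether background of dim probes is the cause. Interval and percentiles treat the genes as independent and the arrays as fixed, so they do not measure the spread between arrays. For the dimmer members background stays open as well. In the mutant its median turned from −0.05 as deposited (percentile 88.7) to 0.14 after quantile normalization (percentile 91.53), which leaves a response to either transgene open.

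The falls of single probes in the mutant could be defects of single spots. Of 8 such probes, 3 belonged to a gene with another probe past the filter, and relative to all probes these other probes gave a median of 0.347 log2 units, with RNFT1 at 0.75, IGSF3 at 0.35 and CFAP90 at −1.81. The median lies above the bound of −0.5 set for a loss of spots, but 3 genes are too few to decide. Other probes left out by the filter read −0.10 for KCNJ13 and 0.24 for TTN, and which probes report their transcript stays open.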

How the results depend on the processing

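Alternatives were fixed before the data were examined except for equalized background and loess with a stricter filter, which were chosen after the results were seen. The number of arrays, with 2, 2 and 1 per group, limits every count. Replicates of a group were no closer than empty vector and ACOT12 arrays were to each other, and median centring led limma to an infinite prior, under which counts are large. Across genes, deviations of same-numbered empty vector and ACOT12 arrays from their group means correlated at r = 0.158 as deposited and 0.193 after quantile normalization. That single comparison neither shows nor excludes a pairing of same-numbered arrays. The cause of each difference below was not tested.

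For ACOT12 against empty vector, 0 genes passed. The count was 21 with a fold rule, 2 with quantile normalization, 45 (18 higher, 27 lower) with centring, 2 with loess, 1 with a 10th percentile offset, 192 (191 higher) without a filter, 8 with probes averaged, 1 with trend and robust variance and 1 with equalized background. Leaving out 1 array gave 0 to 5. The ACOT12 difference of 7.15 was 6.61 with quantile normalization, 7.02 with centring, 7.03 with loess, 5.70 with the offset and 5.33 with equalized background. It stayed at 7.15 but passed without a filter, with probes averaged and with trend, and leaving out 1 array gave 6.32 to 7.98. The 6 lists became 0 with an estimated correlation, 1 with quantile normalization, 1 with loess, 17 without a filter, 14 with probes averaged, 14 per probe and 2 with equalized background, and 2 to 16 with 1 array left out. Their 2 higher and 4 lower became 6 and 1 with the 50th percentile, 5 and 1 with loess and that filter, 3 and 1 with centring, and 5 and 2 without ACOT12 replicate 1.

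For the mutant against empty vector, 5 genes passed. The count was 1218 with a fold rule, 753 at an adjusted p of 0.1, 8 with quantile normalization, 1446 with centring, 187 with loess, 8 with the offset, 150 (137 higher) without a filter, 141 above the 50th percentile, 11 with probes averaged, 499 with trend, 0 without moderation, 9 with equalized background and 137 with loess and the 50th percentile. Leaving out 1 array gave 0 to 2023. ACOT12 (6.90) was 6.44 with quantile normalization, 7.18 with centring, 7.14 with loess, 5.45 with the offset, 5.09 with equalized background and 6.07 to 7.73 with 1 array left out. The 0 lists became 1 with centring, 1 above the 50th percentile, 2 per probe, 1 with equalized background and 0 to 3 with 1 array left out.

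For ACOT12 against the mutant, 1389 genes passed. The count was 2280 at an adjusted p of 0.1, 5 with quantile normalization, 2022 with centring, 1043 (83 lower) with loess, 1 without a filter, 638 above the 50th percentile, 0 without moderation and 543 with loess and the 50th percentile. Leaving out 1 array gave 0 to 2379. ACOT12 (0.25) was 0.16 with quantile normalization and turned to −0.16 with centring and −0.11 with loess, without passing in any of them, and lay between 0.23 and 0.27 with 1 array left out. The 6 lists became 0 with an estimated correlation, 0 with quantile normalization, 1 with centring, 0 with loess, 10 without a filter, 1 above the 50th percentile, 0 with loess and the 50th percentile and 3 to 6 with 1 array left out. The correlation of the effects (−0.061) was 0.057 with loess, 0.676 without a filter, 0.043 with probes averaged, 0.056 with loess and the 50th percentile, 0.249 and −0.44 with unshared controls and −0.138 to 0.315 with 1 array left out. RNFT1 turned to 0.59, 0.68, 0.63 and 0.63 for the mutant against empty vector and to −0.59, −0.59, −0.47 and −0.70 for ACOT12 against the mutant with 1 array left out, because another of its probes was then the brightest.

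The replicate number as a block assumes a pairing that was neither shown nor excluded. With it, 1 gene passed for ACOT12 against empty vector (ACOT12 itself at 7.15). For the mutant against empty vector 1635 genes and 3 lists passed (ACOT12 6.49), and for ACOT12 against the mutant 2485 genes (ACOT12 0.66, not past the threshold).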

Other observations

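The contrasts in this part were chosen after the results were seen, and so were the genes named outside the naming rule.

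With the mean of both transgenes against empty vector, 4 genes passed (limma), with ACOT12 as the 1 higher gene and TSPYL5 (−2.67 ± 0.16, adjusted p = 0.0336) among the lower. None of the other genes named here passed. TAGLN, an actin-binding protein, read 1.44 ± 0.25 higher and MYL9, a myosin light chain, 1.17 ± 0.17. CDA read 1.16 ± 0.15 higher, IL32 1.19, KRT7 1.11, the lysyl oxidase gene LOXL4 1.07, the laminin chain LAMB3 0.88 and the activin-binding protein FSTL3 0.86. Lower readings came from ALB (−1.33), the alcohol dehydrogenases ADH1A (−1.03) and ADH1C (−1.03), FBP1 (−0.87), CD24 (−1.23 ± 0.15), ITM2A (−1.28) and the sterol transporter ABCG1 (−1.17). No list was tested in this contrast, and the list of hepatocyte genes was called neither for ACOT12 (camera, adjusted p = 0.910) nor for the mutant (adjusted p = 0.256) against empty vector. The 3 transgene arrays did not overlap the 2 empty vector arrays for 2512 genes (16.7%), where chance gives 20%.

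With ACOT12 against the mean of empty vector and mutant, 2 genes passed, both higher, and the arrays did not overlap for 2649 genes (17.6%, chance 20%). In this contrast TWIST2 ranked 1873 of 15053 by p (−0.47 ± 0.14, limma adjusted p = 0.138). The transcription factor TBX6 read −0.79, the DNA methyltransferase DNMT3B −0.39 and the membrane protease MMP16 −0.55.

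Among probes without a gene name, PH_hs_0062978 read 666 and 645 with empty vector, 294 and 247 with ACOT12 and 272 with the mutant. Its difference was −1.28 with ACOT12.

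The 1386 genes higher with ACOT12 than with the mutant had a median log2 intensity of 9.26 against 11 for all genes. In the dimmest 10% of probes the mutant array read 1.05 and empty vector replicate 2 −0.47 relative to the empty vector mean.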
